A study of Mus musculus with 8 samples.

How the data were processed

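Cells of the ventricular-subventricular zone (V-SVZ), the germinal layer that lines the lateral ventricles of the adult mouse brain, were profiled by single-cell RNA sequencing. The labels give 8 samples in 4 groups, male or female and lateral or septal wall, with replicates 1 and 2 in each group. Per the labels' protocols, the cells were dissociated and captured on an automated microwell array without sorting, messenger RNA was taken up on beads carrying oligo-dT, and complementary DNA was amplified by PCR and made into Nextera XT libraries. The animals carried a tamoxifen-inducible Cre under the human GFAP promoter together with a tdTomato reporter, except that the strain given for the male septal replicate 2 sample lacks the Cre. The number of animals stated for a sample was 2 for male lateral replicate 1, 2 for male septal replicate 1, 3 for female lateral replicate 1, 3 for female septal replicate 1, 1 for male lateral replicate 2, 3 for male septal replicate 2, 2 for female lateral replicate 2 and 2 for female septal replicate 2. Whether the lateral and septal samples of a number came from the same animals was not given in the sources used here, so p-values measure the spread between these samples.

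The authors deposited whole-number molecule counts per gene and cell, not normalized, in 1 table for the replicate 1 samples (29319 cells and 48526 genes) and 1 table for the replicate 2 samples (13055 cells and 48529 genes). All values in both tables were whole. STAR 2.5.0 and the mouse build GRCm38 are named in the submitters' processing notes. The read counter, the collapsing of unique molecular identifiers (UMIs) and the filter on cells were not given in the sources used here. Other deposited text, per the labels, gives the name of each cell, which holds its sample, and the authors' cell type annotation, which supplied all cell classes. The tables have no column names, so cell names and classes were joined to their columns by position, which was checked through the numbers of cells, sex-linked genes per sample and class markers. Differences in the spelling of a class between the tables were evened out. How the annotation was made, and whether it was made for both tables jointly, was not given in the sources used here. Cells that the authors annotated as doublets occur in the replicate 1 table and were left out of shares and tests, and no further doublet caller was run. The 48525 genes present in both tables were used, and 48143 of them were matched by identifier to GENCODE M21, the source of all coordinates (GRCm38).

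Counts were summed per sample and annotated class, since cells are not replicates. A sample with fewer than 20 cells of a class was left out of its fit, and a class was tested with at least 6 samples and all 4 groups, which left 10 classes. OPC and COP fits had 7 samples, without male lateral replicate 2. Sums were tested with the quasi-likelihood F test of edgeR 4.0.16 (TMM normalization, filterByExpr on the 4 groups) in R 4.3.3. Sex and wall entered as additive terms for the contrasts lateral minus septal and female minus male (5 residual degrees of freedom with 8 samples). A separate fit held their interaction. P-values were adjusted by the Benjamini-Hochberg method within each class and contrast, with a threshold of 0.05. CPM values were computed here from the deposited counts. They are counts scaled to the TMM-adjusted total of the genes tested in that class and sample. They are given as mean ± SD over the samples of a wall or sex. Where CPM of all UMIs are given, the total UMI count of the sample was used instead. Log2 fold changes are the fitted values of edgeR with their standard errors. Shares of 11 annotated classes were compared as log2 odds (0.5 added to both numbers of cells) with a two-sided exact permutation test over the 70 assignments of 8 samples into 4 and 4, adjusted over 22 tests. The smallest p this test can give is 0.0286. Intervals for single shares are exact binomial at 95% and cover counting error only.

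Gene lists (44, of cell type markers, pathways and sex-linked genes) were written before the data were examined, as were the tests, the rule for named genes and the alternatives. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over the lists within a class and contrast, and again with the correlation estimated from the data. Which lists are described was decided after the list results were seen. Medians of a list within each sex were taken after that too, and the difference between the sexes was not tested for lists.

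Genes named for the walls in the astrocyte class were the 12 with the largest and the 12 with the smallest log2 fold change among those with an adjusted p under 0.05, an average log2 CPM of at least 5 and the same sign in all 4 pairs of samples of the same sex and number. The same rule gave up to 8 each way for sex in this class, up to 4 each way for the walls and 3 each way for sex in other classes, with passing members of the sex lists always named. For the interaction it gave up to 6 genes with the smallest adjusted p. Up to 4 members with the smallest p were taken from each described list, and every passing member of the 3 patterning lists. Genes named outside this rule are identified as such.

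Alternatives were DESeq2 1.42.0, RLE size factors in edgeR, no filter on low counts, the replicate number as a block, equal numbers of cells per sample, 1 factor alone in the model and each sample left out in turn. For shares they were neural cells only, permutation within pairs, and edgeR on cell numbers. After the data were seen, equal total counts and each deposited table alone were added. The testing steps were run first on simulated counts with the real means and depths, in which 200 genes were changed by 2-fold or 4-fold. For lateral against septal, 57% of the 4-fold and 8% of the 2-fold changes were recovered in the astrocyte class among 11557 genes, 36% and 2% among 9754 genes in the aNSC+TAC+NB class, 84% and 18% among 4301 genes in ependymal cells, and 50% and 0% among 8047 genes in neurons. Of 73, 39, 108 and 53 calls in these classes, in the same order, 8, 1, 6 and 3 were of unchanged genes. The simulated counts held no difference between the deposited tables beyond depth. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.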

Results

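Cells of the lateral and septal walls of the V-SVZ were compared in male and female mice, to ask which cell classes and which genes differ between the walls and between the sexes. The data hold 42374 cells in 8 samples, 2 in each of 4 groups, so that each wall and each sex had 4 samples. Replicate 1 samples and replicate 2 samples lie in separate deposited tables. In replicate 1, the total UMI count was 12109471 over 6973 cells in the male lateral sample and 4221066 over 4209 cells in the male septal sample. It was 11731780 over 8994 cells in the female lateral sample and 10395095 over 9143 cells in the female septal sample. In replicate 2, it was 2159444 over 1716 cells, 2614882 over 4897 cells, 3924663 over 3217 cells and 2286661 over 3225 cells, in the same order of groups. The median UMI count per cell ranged from 357 in male septal replicate 2 to 1260 in male lateral replicate 1, and the lowest UMI count of any cell from 116 to 617 in the same 2 samples. Numbers of cells equalled the retained cells given in the labels. Xist, the RNA that silences 1 X chromosome in females, was at 158, 469, 127 and 72.2 CPM of all UMIs in female lateral replicate 1, female septal replicate 1, female lateral replicate 2 and female septal replicate 2, and at most 0.926 in any male sample. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d together were at 83.0 to 140 CPM in male samples and at most 2.55 in female samples, so the sex labels matched the counts.

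Mean shares of cell classes were compared between the 2 walls, by a permutation test whose adjusted threshold needs at least 13 of the 22 tests at the smallest possible p. That none passed it thus says little. Cells of the class annotated aNSC+TAC+NB, in the usual reading activated neural stem cells, transit amplifying cells and neuroblasts, were 23.3% ± 6.96 of annotated cells in the lateral wall and 5.56% ± 1.37 in the septal wall (SD, n = 4). The lowest lateral share of this class was 17.9% (95% exact binomial interval 16.6% to 19.3%) and the highest septal share 6.92% (6.06% to 7.85%). Ependymal cells, the ciliated lining of the ventricle, were 1.37% ± 0.474 of lateral and 3.80% ± 1.85 of septal cells, and committed oligodendrocyte precursors (COPs) 0.658% ± 0.253 of lateral and 1.88% ± 0.792 of septal cells. In replicate 2, 7.14% to 34.9% of cells of the COP class held no UMI of the COP markers, against at most 2.04% in replicate 1, and the highest of these was male septal replicate 2, which also had the highest COP share (3.04%). Depth differed too. The median UMI count of COP class cells was 467 in that sample and 634 in female septal replicate 2, against 1751 to 2815 in replicate 1. Missing marker UMIs thus need not mean cells of another kind. Male lateral replicate 2 held 5 COP class cells. Microglia were 19.8% ± 6.63 of lateral and 9.78% ± 5.66 of septal cells. Neurons were 3.05% ± 0.532 of lateral and 13.8% ± 11.4 of septal cells.

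**Figure D1:**
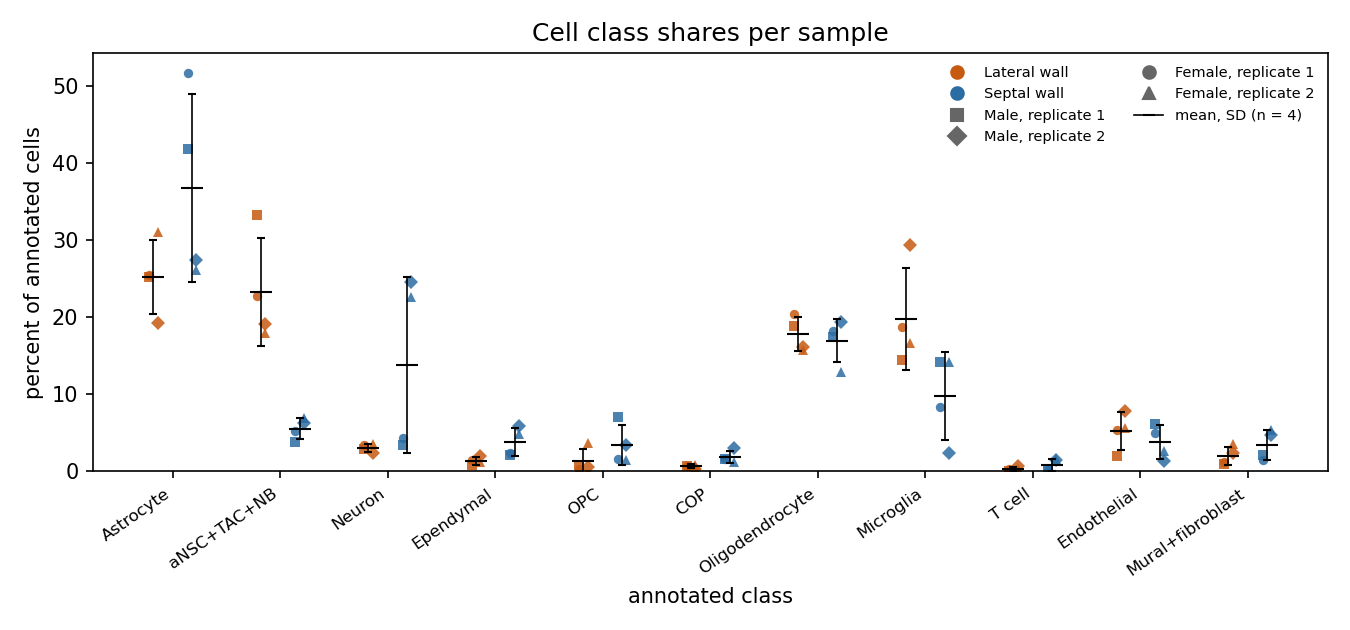
The share of each annotated class among the annotated cells of a sample, in percent (vertical axis), for 11 classes (horizontal axis), with lateral samples in orange and septal samples in blue, a marker shape for each sex and replicate, and black bars for the mean and SD of 4 samples. The lateral aNSC+TAC+NB shares all lie at or above 17.9% and the septal shares at or below 6.92%.

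The log2 odds of the aNSC+TAC+NB share differed by 2.36 (SE 0.335), an odds ratio of 5.13, with the lateral wall higher in 4 of 4 pairs of samples of the same sex and number. The difference was 3.04 within replicate 1 and 1.68 within replicate 2. Its exact permutation p was 0.0286, the smallest the test can give, and 0.157 after Benjamini-Hochberg adjustment over 22 tests. Ependymal cells (log2 odds difference -1.43, -1.04 and -1.82 within replicates 1 and 2), COPs (-1.52, -1.13 and -1.92) and microglia (1.43, 0.68 and 2.17) had the same exact permutation p of 0.0286 and adjusted p of 0.157, each with 1 direction in 4 of 4 pairs. For microglia both rest on a close pair, 14.42% in male lateral replicate 1 and 14.21% in male septal replicate 1. Their binomial intervals overlap (13.58% to 15.29% and 13.16% to 15.3%). Annotated doublets left out were 372 cells in the first sample and 14 in the second. Microglial shares with doublets counted were not computed. The neuron share differed by -1.84 (exact permutation p = 0.0857, adjusted p = 0.377), with -0.31 within replicate 1 and -3.36 within replicate 2, where 24.6% and 22.6% of the male and female septal cells were neurons. Astrocytes (25.2% ± 4.82 lateral and 36.8% ± 12.2 septal) differed by -0.77, with -1.37 and -0.16 within replicates 1 and 2. OPCs, the oligodendrocyte progenitor cells (1.33% ± 1.55 and 3.38% ± 2.59), differed by -1.73, with -2.87 and -0.60, and oligodendrocytes (17.8% ± 2.21 and 17.0% ± 2.83) by 0.09, with 0.17 and 0.01. Their exact permutation p-values were 0.143, 0.143 and 0.686. By contrast, edgeR on cell numbers called the aNSC+TAC+NB share alone (log2 difference 2.06, adjusted p = 0.0182). Shares are of cells that survived dissociation, capture and the authors' filter, and the lowest UMI count of a cell differed between samples (116 to 617).

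In the astrocyte class, which was annotated without a separate class of quiescent stem cells, the serine protease gene Prss56 and the chemokine gene Cxcl5 marked opposite walls. Prss56 was at 233 ± 88.7 CPM in the lateral and 5.11 ± 1.93 CPM in the septal wall (SD, n = 4), a log2 fold change of 5.61 (SE 0.405, adjusted p = 0.000416). Its mean difference of log2 CPM was 5.63 within replicate 1 and 4.61 within replicate 2. Cxcl5 was at 1.28 ± 1.92 CPM in the lateral and 151 ± 42.7 CPM in the septal wall (log2 fold change -6.99, SE 0.579, adjusted p = 0.000832, and -6.62 and -5.38 within replicates 1 and 2). Zic1 and Zic4, adjacent genes for zinc finger transcription factors of the medial and dorsal neural tube, fell by 4.25 and 4.94 on the log2 scale in the lateral wall. Zic1 went from 169 ± 7.64 to 11.2 ± 7.49 CPM (SE 0.445, adjusted p = 0.00425, and -4.70 and -3.32 within replicates 1 and 2). Crym, which encodes a thyroid hormone binding protein, was the most abundant of the lateral genes named, at 2213 ± 551 against 467 ± 196 CPM (log2 fold change 2.27, SE 0.331, adjusted p = 0.0173, and 2.80 and 1.77 within replicates 1 and 2).

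Other genes higher in lateral astrocytes were Sfrp1 and Dkk3, for secreted proteins that act on Wnt signalling (99.1 against 22.1 and 506 against 138 CPM), Thbs4 for thrombospondin 4 (73.1 against 17.8), Igfbp5 (271 against 83.1), Tnfrsf19 (126 against 42.4) and Gdf10, Nupr1, Gm2115, Rlbp1 and Ppp1r3g. Their log2 fold changes were 1.59 to 2.58 and their adjusted p-values 0.00210 to 0.0418. Nupr1 was also present in lateral microglia, at 1.60 times its UMIs per cell in lateral astrocytes. Genes higher in septal astrocytes included Gria1, for a subunit of AMPA-type glutamate receptors (148 against 16.6 CPM), Igsf1 (308 against 32.6), Agt, for angiotensinogen (1540 against 244), Itih3 (935 against 160), Etnppl (212 against 45.2), Hopx (159 against 39.9), Cntnap2 and Cacng5. These had log2 fold changes of -3.45 to -2.10 and adjusted p-values of 0.00642 to 0.0229. Olig2, a transcription factor of the oligodendrocyte lineage, was at 120 ± 11.8 CPM in septal and 24.4 ± 8.64 CPM in lateral astrocytes (log2 fold change -2.27, SE 0.263, adjusted p = 0.00642). Oligodendrocytes of the septal wall held 3.76 times as many Olig2 UMIs per cell as septal astrocytes. Prss56 (ENSMUSG00000036480.9) is at positions 87183313 to 87188405 of chromosome 1 and Cxcl5 (ENSMUSG00000029371.7) at 90759360 to 90761624 of chromosome 5. Zic1 (ENSMUSG00000032368.14) is at 91358058 to 91365810 and Zic4 (ENSMUSG00000036972.14) at 91362413 to 91389348 of chromosome 9, where they overlap on opposite strands. Crym (ENSMUSG00000030905.5) is at 120186380 to 120202111 of chromosome 7, and all 5 genes are protein-coding in GENCODE M21 (GRCm38). Whether the authors' counting used strand was not given in the sources used here, so reads of the overlapping part of Zic1 and Zic4 are uncertain between them.

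**Figure D2:**
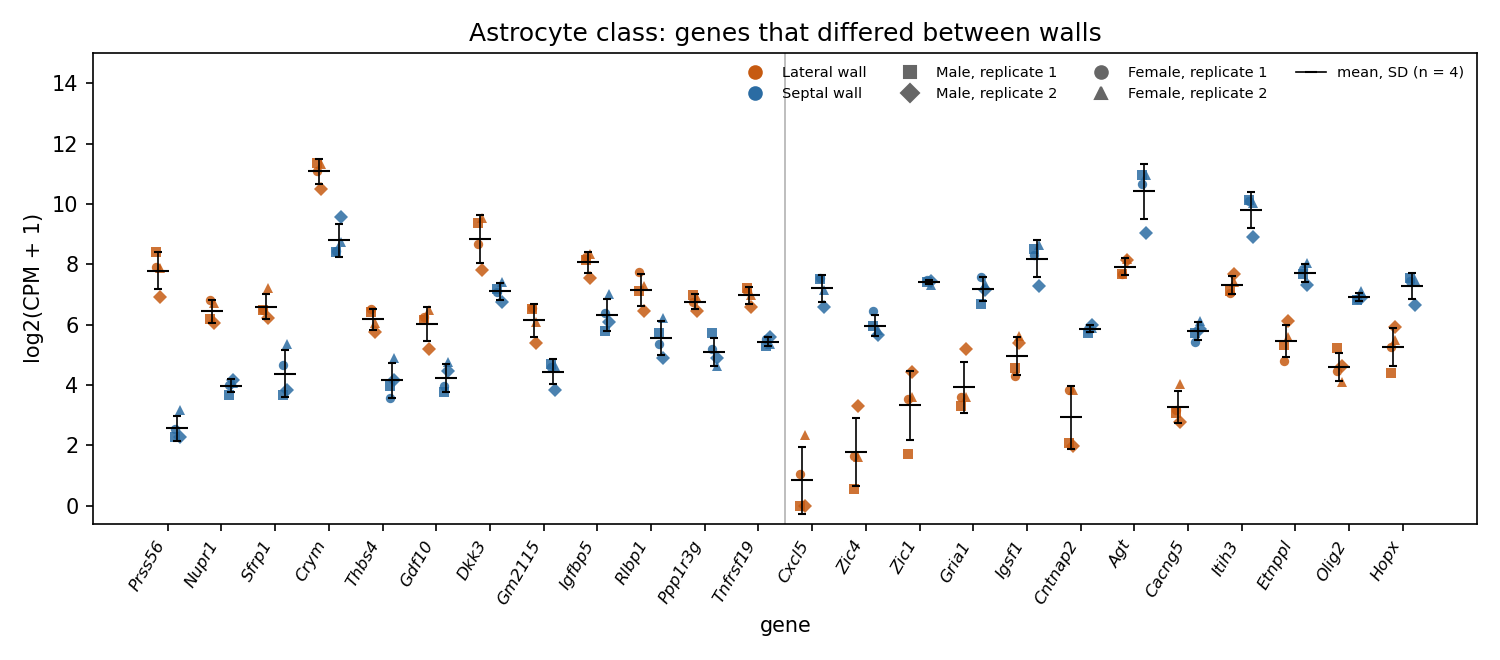
Expression of the 24 genes named for the walls in the astrocyte class (horizontal axis) as log2(CPM + 1) of the summed counts of each sample (vertical axis), with lateral samples in orange, septal samples in blue, a marker shape for each sex and replicate, and black bars for the mean and SD of these log values over 4 samples. The 12 genes left of the grey line are higher in the lateral wall, Prss56 first, and the 12 to its right higher in the septal wall, Cxcl5 first.

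Across 11557 genes tested in astrocytes (325986 to 3797075 UMIs per sample), 27 were higher and 43 lower in the lateral wall by the quasi-likelihood test of edgeR, and all 70 had the same sign in 4 of 4 pairs. DESeq2 called 203 genes, among them all 70. With equal numbers of cells per sample 21 passed, and with equal total counts 6. In the replicate 1 table alone all 70 had the same sign, as had all 68 that were tested in the replicate 2 table alone. The 70 genes were called with these same samples, so the shared sign, in pairs or in a table, is no independent support. A table alone has 1 sample per group and 1 residual degree of freedom, so passing there rests on little estimate of spread. Prss56, Cxcl5, Zic1, Zic4, Gria1, Igsf1, Itih3 and Olig2 passed with DESeq2, RLE size factors, no filter on low counts, the replicate block, equal numbers of cells, the wall alone in the model, each sample left out in turn and each table alone. With equal total counts, only Prss56 and Itih3 of these 8 passed (adjusted p = 0.0201 and 0.0223), and the others had adjusted p-values of 0.0936 to 0.978 with log2 fold changes of -4.40 to -2.52. All 56 of the 70 genes that were tested there had the same sign, in counts drawn from the same samples. The count was 14 without female septal replicate 1, 15 without female lateral replicate 2, 17 without female lateral replicate 1, and 26 without female septal replicate 2. It was 27 without male septal replicate 1, 35 without male lateral replicate 1 and 158 without male lateral replicate 2. In that order 12, 11, 13, 16, 15, 19 and 24 of the 24 named genes passed.

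Among transcription factors and signals that pattern the forebrain, those listed for the medial and septal region were mostly higher in septal astrocytes. Zic1 and Zic4 fell in the lateral wall among 9 members tested, and 7 members fell when adjusted over the list alone. Zic2 was at 1.16 ± 1.76 lateral and 10.3 ± 3.83 septal CPM. The list was lower in the lateral wall (median log2 fold change -1.86, camera adjusted p = 1.07e-06, adjusted p = 0.137 with an estimated correlation). Of 14 members listed for the ventral and lateral wall, none passed over all genes by edgeR, and 1 rose and 1 fell when adjusted over the list alone. Meis2 was at 159 ± 38.1 lateral and 84.6 ± 21.8 septal CPM and Otx2 at 10.1 ± 5.14 and 38.4 ± 14.5 (list camera adjusted p = 0.827, adjusted p = 0.941 with an estimated correlation). Of 5 dorsal pallial members, 2 rose and 1 fell when adjusted over the list alone and none over all genes. Nr2e1 (Tlx) was at 273 ± 46.8 lateral and 149 ± 29.4 septal CPM and Emx1 at 3.54 ± 2.43 and 16.3 ± 6.86 (list camera adjusted p = 0.752, adjusted p = 0.890 with an estimated correlation).

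Of 15 markers enriched in quiescent neural stem cells, Id3 (1480 ± 238 against 513 ± 87.5 CPM), Id1 (194 ± 61.0 against 68.0 ± 12.5) and Thbs4 rose and Hopx fell in the lateral wall over all genes. Adjusted over the list alone, 5 rose and 1 fell (median log2 fold change 0.43, camera adjusted p = 0.00913, adjusted p = 0.326 with an estimated correlation). Of 12 markers of activated stem and transit amplifying cells, none passed over all genes and 1 rose when adjusted over the list alone. Ccnd2, for cyclin D2, was at 191 ± 55.9 and 74.3 ± 35.5 CPM (list camera adjusted p = 0.0274, adjusted p = 0.329 with an estimated correlation). Of 17 genes of glutamate and GABA handling, Gria1 and the glutamine transporter gene Slc38a1 fell in the lateral wall over all genes and 5 fell when adjusted over the list alone. The GABA transporter gene Slc6a11 was at 746 ± 155 lateral and 1932 ± 706 septal CPM (list camera adjusted p = 0.00913, adjusted p = 0.444 with an estimated correlation). Of 10 Hedgehog pathway members none passed over all genes and 4 fell when adjusted over the list alone (camera adjusted p = 0.0161, adjusted p = 0.535 with an estimated correlation). Among them was the receptor and target gene Ptch1 at 122 ± 32.2 lateral and 305 ± 87.9 septal CPM (log2 fold change -1.35, adjusted p = 0.0715).

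Markers of other cell types moved with the wall in the astrocyte class. All 13 OPC markers had lower values in lateral astrocytes, 2 past the threshold over all genes (Olig1, 108 ± 27.5 against 270 ± 32.3 CPM, and Olig2) and 8 when adjusted over the list alone. The median log2 fold change was -1.65 (camera adjusted p = 3.34e-12, adjusted p = 0.320 with an estimated correlation). All 7 fibroblast markers, of which Pdgfra is also an OPC marker, had lower values in the lateral wall, 4 of them when adjusted over the list alone and none over all genes (median -1.66, camera adjusted p = 8.99e-06, adjusted p = 0.137 with an estimated correlation). All 12 ependymal markers were lower (median -0.64) and all 14 microglial markers higher (median 0.53) in the lateral wall with none past the threshold. The camera adjusted p-values were 0.00680 and 0.0347 (adjusted p = 0.609 and 0.788 with an estimated correlation). Of neuron markers, 11 of 12 were lower in the lateral wall, none past the threshold over all genes or over the list alone (median -1.13, camera adjusted p = 0.0562, 0.0260 with the replicate number as a block, adjusted p = 0.788 with an estimated correlation). Of COP markers, 5 of 7 were lower, 3 of them when adjusted over the list alone and none over all genes (median -0.63, camera adjusted p = 0.0274, adjusted p = 0.326 with an estimated correlation). Immediate-early genes went both ways, 9 higher and 8 lower (median 0.58, camera adjusted p = 0.0274, adjusted p = 0.732 with an estimated correlation). Mitochondrially encoded transcripts, a sign of cell quality, were higher in 11 of 12 cases (median 0.89, camera adjusted p = 0.0196, adjusted p = 0.788 with an estimated correlation). Of these lists, 3 went opposite ways in the sexes: the median lateral minus septal difference of log2 CPM was 1.01 in males and -0.16 in females for microglial markers, 0.69 and -0.06 for immediate-early genes and 2.36 and -0.75 for mitochondrial transcripts.

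In the aNSC+TAC+NB class no single gene passed between walls by edgeR among 9754 tested (484 at an unadjusted p under 0.05), and DESeq2 called 46. The medial and septal patterning list had the largest median of the lists described for this class, -2.91 over 8 members. Zic1 was at 24.6 ± 16.1 lateral and 336 ± 61.5 septal CPM (log2 fold change -3.96, SE 0.607, adjusted p = 0.274). Zic4 was at 2.90 ± 3.12 and 61.4 ± 19.4 CPM (log2 fold change -5.21, SE 0.745, adjusted p = 0.247). Zic5 was at 6.64 ± 2.96 lateral and 52.5 ± 27.9 septal CPM, while Nr2f1, for a nuclear receptor in the same list, was at 54.7 ± 12.1 lateral and 12.6 ± 7.19 septal CPM. None of the 8 passed over all genes, and 5 fell and 1 rose when adjusted over the list alone (camera adjusted p = 5.46e-07, adjusted p = 0.281 with an estimated correlation). Among neuroblast markers, Meis2 was at 492 ± 153 and 229 ± 66.0 CPM and Nrep at 462 ± 47.1 and 224 ± 25.4 CPM. Of 20 tested, none passed over all genes and 2 were higher in the lateral wall when adjusted over the list alone (camera adjusted p = 0.0113, adjusted p = 0.528 with an estimated correlation). Immediate-early genes, which respond to dissociation, had higher lateral values for 15 of 16 members in this class (median 0.69, camera adjusted p = 2.70e-07, adjusted p = 0.281 with an estimated correlation). Markers of other cell types moved too. All 11 microglial markers (median 1.22) and all 5 red blood cell genes (median 1.13) had higher lateral values, and 11 of 13 neuron markers (median -0.70) and 5 of 7 OPC markers (median -1.44) lower ones. None passed over all genes, and 3 neuron and 4 OPC markers fell when adjusted over the list alone. Their camera adjusted p-values were 0.000159, 0.000510, 0.000436 and 0.000510 (adjusted p = 0.555, 0.555, 0.555 and 0.550 with an estimated correlation). Sums of this class ranged from 219510 to 4312201 UMIs per sample. The count was 1 without male lateral replicate 1 and 2 without male lateral replicate 2.

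In the ependymal class, Zic1 and Zic4 differed between walls, and so did haemoglobin genes. Zic1 was at 3.75 ± 7.50 lateral and 173 ± 23.5 septal CPM (log2 fold change -4.69, SE 0.584, adjusted p = 0.00161) and Zic4 at 3.75 ± 7.50 and 163 ± 29.7 CPM (-4.61, SE 0.597, adjusted p = 0.00161). The keratin gene Krt15 (12.6 ± 16.8 against 160 ± 35.7 CPM) and Emb, for embigin (13.5 against 139), were also lower in the lateral wall. Hba-a1 was at 5335 ± 4294 lateral and 208 ± 136 septal CPM (log2 fold change 4.75, SE 0.604, adjusted p = 0.00161), and Hba-a2, Hbb-bt and Hbb-bs rose by 4.62, 4.71 and 3.57. These transcripts belong to red blood cells, and the split of reads between near-identical haemoglobin copies is uncertain. Of 4301 genes tested (38675 to 273612 UMIs per sample), 9 rose and 8 fell by edgeR, and 23 passed by DESeq2. All 17 genes kept their sign in each table alone, but they were called with these same samples, so this is no independent support. With equal numbers of cells 6 passed and with equal total counts 4. The count was 7 without female lateral replicate 2. Of 9 neuroblast markers none passed over all genes and 4 rose when adjusted over the list alone. Tubb3 was at 123 ± 71.5 lateral and 20.7 ± 26.8 septal CPM (list camera adjusted p = 5.69e-05, adjusted p = 0.111 with an estimated correlation). All 8 mitochondrial transcripts (median 1.12) and 9 of 11 immediate-early genes (median 0.52) had higher lateral values (camera adjusted p = 0.000131 and 0.0367, adjusted p = 0.529 each with an estimated correlation). Both lists went opposite ways in the sexes (median difference of log2 CPM 1.82 in males and -0.10 in females for mitochondrial transcripts, and 0.75 and -0.05 for immediate-early genes). Astrocyte marker UMIs outnumbered ependymal marker UMIs in the ependymal class of all 8 samples. The lists differ in length, so which sum is larger does not measure how many astrocytes the class holds. In replicate 2, 12.2% to 24.3% of ependymal cells held no UMI of the ependymal markers, against at most 5.62% in replicate 1.

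In neurons, Syndig1l (257 ± 177 against 30.5 ± 18.1 CPM) and Nexn (112 ± 60.4 against 10.3 ± 7.92) rose in the lateral wall, by 3.08 (SE 0.494) and 3.21 (SE 0.584). Pnoc, which encodes the precursor of nociceptin, was at 3.82 ± 4.81 lateral and 125 ± 120 septal CPM (log2 fold change -4.82, SE 0.874). The receptor gene Gfra2 was at 4.99 ± 9.98 and 101 ± 28.3 CPM, Cacng5 at 2.21 ± 2.65 and 76.0 ± 50.9 CPM, and Gpx3 at 4.43 ± 5.30 and 110 ± 83.9 CPM. Adjusted p-values of these 6 genes were 0.0450 to 0.0492 by edgeR, which called 2 genes higher and 5 lower among 8047, while DESeq2 called 49. With the replicate number as a block none passed, with adjusted p-values of 0.0600 to 0.0736 for these 6 and log2 fold changes of 3.10 for Syndig1l and -4.87 for Pnoc. Zic5 (1.32 ± 2.64 against 61.3 ± 28.8 CPM) and Zic4 (4.99 ± 9.98 against 53.0 ± 3.47) had adjusted p-values of 0.0615 and 0.109. Of 7 tested medial and septal patterning genes none passed over all genes and 4 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000625, adjusted p = 0.301 with an estimated correlation). All 11 mitochondrial transcripts had higher fitted lateral values (median 1.78, camera adjusted p = 1.11e-05, adjusted p = 0.766 with an estimated correlation). This direction did not hold in both sexes: the median difference of log2 CPM was 3.11 in males and -0.32 in females, with mt-Atp8 at 4.39 and -1.15. Other lists also moved in the neuron class. All 10 microglial markers (median 1.45), all 13 oligodendrocyte markers (median 0.60), 20 of 25 astrocyte markers (median 0.39), 11 of 13 immediate-early genes (median 0.65) and 70 of 78 cytosolic ribosomal protein genes (median 0.35) had higher lateral values. None passed over all genes, and their camera adjusted p-values were 4.22e-06, 0.00642, 0.0288, 0.00113 and 0.000468 (adjusted p = 0.766, 0.867, 0.867, 0.766 and 0.867 with an estimated correlation). Astrocyte markers went opposite ways in the sexes (median difference of log2 CPM 1.20 in males and -0.40 in females). The shift of 3 other lists lay mainly in males. Their medians in males and females were 2.25 and 0.25 for microglial markers, 1.36 and 0.007 for oligodendrocyte markers and 1.33 and 0.05 for immediate-early genes. Ribosomal protein genes were at 0.29 and 0.28. Astrocyte marker UMIs outnumbered neuron marker UMIs in the neuron class of male lateral replicate 1 and female septal replicate 1. These lists too differ in length, so this does not measure how many astrocytes the class holds. Lateral samples held 41 to 299 neurons and 31688 UMIs in the smallest sum, and no gene passed by edgeR with equal numbers of cells per sample or equal total counts. All 7 genes had the same sign in each table alone, but they were called with these same samples, so this is no independent support. The count was 149 without female septal replicate 1, 19 without female lateral replicate 2, and 17 without male septal replicate 2. It was 1 without either male lateral sample and 0 without male septal replicate 1 or female lateral replicate 1.

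In oligodendrocytes, microglia, COPs, endothelial cells and the class of mural cells and fibroblasts, no gene passed between walls by edgeR, with 365, 306, 172, 134 and 149 genes at an unadjusted p under 0.05 and 5, 11, 0, 0 and 2 genes called by DESeq2. In microglia DESeq2 gave adjusted p-values to 1423 genes and edgeR to 8556, so the 2 counts were not adjusted over the same genes. In microglia the perivascular macrophage markers had lower lateral values for all 7 members, with Pf4 at 21.0 ± 13.8 lateral and 349 ± 414 septal CPM (log2 fold change -3.94, SE 0.662, adjusted p = 0.754) and Mrc1 at 20.1 ± 17.1 and 151 ± 198. None of the 7 passed over all genes and 6 fell when adjusted over the list alone (camera adjusted p = 1.02e-10, adjusted p = 0.258 with an estimated correlation). Other markers moved in the same class, with 11 of 15 neuroblast markers higher (median 1.35) and 18 of 24 astrocyte markers lower (median -0.39) in the lateral wall. None passed over all genes, and 5 neuroblast markers rose when adjusted over the list alone (camera adjusted p = 7.82e-06 and 0.000688, adjusted p = 0.368 and 0.642 with an estimated correlation). Astrocyte markers went opposite ways in the sexes (median difference of log2 CPM 0.14 in males and -0.72 in females). Without male lateral replicate 1, 1 gene passed in oligodendrocytes and 2 in endothelial cells, and without male lateral replicate 2, 2 passed in microglia. Omitting female septal replicate 1 gave 1 in microglia, and omitting female septal replicate 2 gave 1 in mural cells and fibroblasts. COPs had 1 without female lateral replicate 1 and 2 without male septal replicate 1. In OPCs Prss56 passed by edgeR (adjusted p = 0.0268, with 171 genes at an unadjusted p under 0.05 and 0 called by DESeq2). All of its 112 UMIs lay in female lateral replicate 2, and it is named here after its values were seen. The OPC count was 5 without female lateral replicate 1 and 0 without male lateral replicate 1, female septal replicate 1 or female septal replicate 2. In replicate 2, 23.5% to 30.0% of cells of the OPC class held no UMI of the OPC markers, against at most 0.694% in replicate 1.

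Between the sexes, genes of the sex chromosomes alone passed the edgeR threshold in any of the 10 classes. Xist was higher in females in 6 classes, at 252 ± 283 against 0.242 ± 0.484 CPM in astrocytes (adjusted p = 0.0287) and with adjusted p-values of 2.97e-06 to 0.00780 in OPCs, COPs, neurons, the aNSC+TAC+NB class and microglia. Ddx3y, for a Y-linked RNA helicase, was higher in males in astrocytes (0.254 ± 0.508 female against 45.6 ± 12.3 male CPM, adjusted p = 0.00307) and oligodendrocytes, and Eif2s3y in oligodendrocytes and microglia. No gene passed in ependymal, endothelial or mural and fibroblast cells by edgeR (130, 162 and 102 at an unadjusted p under 0.05), and DESeq2 called 1 gene in each. DESeq2 called 5 genes in astrocytes, 3 in the aNSC+TAC+NB class and 5 in oligodendrocytes. Without male lateral replicate 1, 42 genes passed in endothelial cells, 19 in oligodendrocytes, 7 in astrocytes and 5 in the aNSC+TAC+NB class. Without female septal replicate 1, 10 passed in OPCs. The other omissions left 0 to 6 genes in each class. For class shares between sexes the exact permutation p was at least 0.543 (adjusted p of at least 0.880 in 11 classes), with SEs of up to 1.37 log2 odds, so a difference was neither shown nor excluded.

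Among lists, X-linked genes known to be higher in females had higher female values for all 8 members in astrocytes, with Xist alone past the threshold over all genes and over the list alone. Ddx3x was at 164 ± 15.5 female and 113 ± 15.6 male CPM, and Kdm6a at 22.1 ± 5.18 and 13.3 ± 7.20 CPM (list camera adjusted p = 2.19e-08, adjusted p = 0.0640 with an estimated correlation). Steroid receptor and response genes had none of 9 past the threshold over all genes or over the list alone. Tsc22d3, a glucocorticoid target, was at 184 ± 46.0 female and 118 ± 23.7 male CPM (list camera adjusted p = 0.0456, adjusted p = 0.326 with an estimated correlation). Astrocyte markers had higher female values for 25 of 26 members (median 0.31, camera adjusted p = 1.17e-06, adjusted p = 0.467 with an estimated correlation). Transcripts of other cell types moved the other way in the same class. All 16 oligodendrocyte markers (median -0.91), all 14 microglial markers (median -1.01), 14 of 15 myelin protein genes (median -0.99), all 5 red blood cell genes (median -1.42) and 70 of 80 cytosolic ribosomal protein genes (median -0.24) had lower female values. Adjusted over the list alone, 1 oligodendrocyte marker, 1 myelin gene and 4 red blood cell genes were lower in females, and none over all genes. Their camera adjusted p-values were 2.88e-13, 2.31e-07, 3.98e-11, 2.31e-07 and 1.48e-09, and with an estimated correlation the adjusted p-values were 0.326, 0.434, 0.326, 0.326 and 0.468. In addition, 17 of 18 neuroblast markers had lower female values (median -0.70) and 10 of 12 mitochondrial transcripts higher ones (median 0.89), none past the threshold over all genes or over the list alone. Their camera adjusted p-values were 0.000102 and 0.0342 (adjusted p of at least 0.541 with an estimated correlation). In mural cells and fibroblasts, all 10 fibroblast markers had higher female values. The collagen-binding proteoglycan gene Dcn was at 1602 ± 1101 female and 368 ± 393 male CPM and Col1a1 at 348 ± 219 and 107 ± 86.9. None passed over all genes and 5 were higher when adjusted over the list alone (camera adjusted p = 1.22e-09, adjusted p = 0.393 with an estimated correlation). In the same class 66 of 68 cytosolic ribosomal protein genes (median -0.43), all 7 myelin protein genes (median -0.98) and 7 of 9 oligodendrocyte markers (median -0.94) had lower female values, none past the threshold over all genes or over the list alone. Their camera adjusted p-values were 4.98e-12, 0.000121 and 0.0210 (adjusted p = 0.495 each with an estimated correlation).

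Whether the walls differed in another way in females than in males was tested as an interaction. In astrocytes no gene passed by edgeR (87 at an unadjusted p under 0.05) or DESeq2. Prss56 differed between walls by 5.28 in males and 4.96 in females, Zic1 by -4.25 and -3.77 and Cxcl5 by -6.55 and -5.46, as mean differences of log2 CPM. In COPs and OPCs, male lateral replicate 1 was the only sample of its group in the fit. Its spread was taken from the other groups, so in these classes an interaction cannot be separated from a deviation of that sample. In COPs 7 genes had a positive and 4 a negative interaction among 5743. The red blood cell genes Hba-a2, Hbb-bs and Hba-a1 were at 5.64, 5.58 and 5.38 (SE 1.04, 1.05 and 1.03), Gm15920 at 6.60, and mt-Rnr2 and mt-Rnr1, the mitochondrial ribosomal RNA genes, at -4.41 and -7.18. Hbb-bs was at 20860 CPM in COPs of female lateral replicate 2 and at 124 to 2561 CPM in the 6 other COP sums. In OPCs Gm15920, Cldn11 and mt-Nd1 passed (5.65, -5.06 and -4.06, adjusted p = 0.0313 each), and in neurons mt-Atp8 (-5.80, SE 0.955, adjusted p = 0.0399). DESeq2 called 0 genes in COPs (120 at an unadjusted p under 0.05 by edgeR), 0 in OPCs and 1 in neurons. Leaving out female septal replicate 1 gave 0 genes in COPs and OPCs and 10 in neurons, and leaving out female septal replicate 2 gave 0 in OPCs and 45 in neurons. Leaving out male septal replicate 1 gave 3 in COPs, 5 in OPCs and 6 in neurons. Without male septal replicate 2 there were 17 in COPs, 5 in OPCs and 0 in neurons, and without female lateral replicate 1 there were 8 in OPCs and 10 in neurons. Without female lateral replicate 2 there were 0 positive and 9 negative in COPs, with 2 of the 6 named genes past the threshold, 3 in OPCs, with 1 of the 3 named, and 3 in neurons, and without male lateral replicates 1 and 2 there were 0 and 2 in neurons. No gene passed in the other 6 classes by edgeR, with 68 to 131 genes at an unadjusted p under 0.05 and 0 to 2 called by DESeq2. Without male lateral replicate 1, 7 genes passed in endothelial cells, 4 in mural cells and fibroblasts, 3 in ependymal cells and 2 in microglia. Ependymal cells had 4 without male septal replicate 1, 3 without female septal replicate 2 and 1 without female lateral replicate 2.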

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

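All splits of the samples into other groups, the free RNA and doublet tests of the OPC class, and the interval around the free RNA ratio of astrocyte genes were tests chosen after the result was seen.

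The first pattern is the set of 70 genes that differed between walls in the astrocyte class. Splits of the 8 samples into 4 and 4 cannot decide on chance, since they were fitted without the deposited table as a term. Of 35 splits, 3, the real one included, called at least 70 genes, with 247 in the highest other. The split by replicate number, which follows the deposited table, called 115. Splits that call several times the real number point to a structure of the samples, and with the replicate number as a block the walls differed in 116 genes. Free RNA of other cell types may add to part of the set: microglia or oligodendrocytes held a median of 0.201 of the astrocyte UMIs per cell (bootstrap 95% interval 0.121 to 0.363 over 2000 draws), with 39 genes under 0.25 and 23 at 0.5 or more. The draws were of the 70 genes, so the interval covers the spread between genes and not between samples. The ratio also counts transcripts that those cells express themselves, so it cannot measure free RNA alone. It was 10.2 for Olig1, and 0.024, 0.042 and 0.034 for Prss56, Cxcl5 and Crym. The median is under the bound of 0.25 set before the test but its interval is not, so this stays open, as does a difference in the cells of the walls themselves, which was not tested.

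The second pattern is the higher level of OPC markers in septal astrocytes, of which Olig1 and Olig2 passed over all genes. If OPCs within the class were the source, their UMIs would have to make up 5.97% to 9.65% of those of septal astrocytes, beyond any in lateral astrocytes. This is a share of UMIs and not of cells. The 11 other OPC markers exceeded by a median of 0.291 of what that needs (mean of 4 pairs, 0.0520 to 0.512), between the bounds of 0.25 and 0.5. Free RNA may contribute, since septal microglia held 0.380 of the Olig1 and 0.150 of the Olig2 UMIs per cell of septal astrocytes. Neither explanation is excluded, and a difference in the septal astrocytes themselves was not tested.

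The third pattern is the astrocyte transcripts, Prss56 among them, in the OPC class of female lateral replicate 2. Free RNA is argued against, since oligodendrocytes of that sample held 0.130 (6.31 against 48.7 UMIs per cell) of the astrocyte marker UMIs of its OPC class. OPC markers argue against doublets of OPCs and astrocytes. The 39 cells rich in astrocyte markers held 0.0997 of the OPC marker UMIs of the 78 others (interval 0.0578 to 0.158), 1.90 against 19.0 UMIs per cell, with 0.993 in the astrocyte class. Total UMIs lean the other way, with a median of 2242 in the 39 cells, 1037 in the 78 others and 783.5 in the astrocyte class of that sample. Choosing cells by marker UMIs favours cells with many UMIs, so these totals do not decide, and doublets of other kinds were not tested. An earlier doublet test, with a ratio of 0.0484, selected cells on the measure it tested and was set aside. Astrocytes annotated as OPCs may be a source, since 29.1% of the class held no OPC marker UMI, but the share was 30.0% in male lateral replicate 2 and 23.5% and 25% in male and female septal replicate 2. These shares are at unlike depth. The median UMI count of OPC class cells was 1327 in female and 1648 in male lateral replicate 2, but 445 and 486 in male and female septal replicate 2. The 10 OPC class cells of male lateral replicate 2, too few for the fit, held 55.2 astrocyte marker UMIs per cell, and 80% of them more astrocyte than OPC marker UMIs, against 57.3% in female lateral replicate 2. Prss56 had 112 UMIs in the 117 OPC class cells and 231 UMIs in the 998 astrocytes of female lateral replicate 2. This is more than average astrocytes of that sample would bring. The CPM values, 790 and 235, were scaled within each class. High astrocyte marker UMIs thus recurred in the 10 cells of male lateral replicate 2. The OPC class of male and female septal replicate 2 held 4.47 and 8.81 of these UMIs per cell. The source of the pattern stays open.

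For the other counts above 0 between walls, the splits cannot decide on chance either. As many genes came from 2 of 35 splits in neurons (real count 7, highest other 77, 2 by replicate number and 0 with the block) and 3 in ependymal cells (17, highest other 33, from the replicate number split, with 22 genes when that number is a block). As many came from 22 splits in OPCs (1, highest other 72, 36 by replicate number and 7 with the block). Where the real count was 0, all 35 splits give as many by construction, which says nothing about chance. In those classes the highest other was 275 in the aNSC+TAC+NB class, 22 in COPs, 203 in oligodendrocytes, 454 in microglia, 164 in endothelial cells and 6 in mural cells and fibroblasts. In microglia and endothelial cells that highest split was the one by replicate number, and the block gave 0 genes in both, as did the real split by edgeR (306 and 134 at an unadjusted p under 0.05, 11 and 0 with DESeq2). Between sexes, as many genes came from 6 of 35 splits in astrocytes (real count 2, highest other 278, 169 by replicate number and 3 with the block) and 8 in the aNSC+TAC+NB class (1, highest other 464, the replicate number split, against 2 with the block). Neurons had 9 such splits (1, highest other 183, 7 by replicate number and 1 with the block), OPCs 21 (1, highest other 69, the replicate number split, and 3 with the block) and COPs 25 (1, highest other 40, 6 by replicate number and 1 with the block). There were 5 in oligodendrocytes (2, highest other 200) and 6 in microglia (2, highest other 359, 267 by replicate number and 2 with the block). In ependymal, endothelial and mural and fibroblast cells the real count was 0, so that all 35 splits give as many by construction (highest other 68, 153 and 22). The high counts of other splits point to a structure of the samples. Splits with as many genes also occurred for sex, where all called genes lie on the sex chromosomes. The splits thus cannot separate chance from that structure.

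Single samples stood apart from the 3 others of their wall or sex in 9 of 115 groups, where chance gives 5.8. In astrocytes, Gria1 was at 35.4 CPM in male lateral replicate 2 against 8.78 to 11.2 in the other lateral samples. Itih3 was at 483 CPM and Hopx at 98.9 CPM in male septal replicate 2, and Olig2 at 137 CPM in female septal replicate 2. In neurons, Gfra2 was at 19.96 CPM (2 UMIs) in female lateral replicate 2 and Xist at 4.41 CPM (1 UMI) in male septal replicate 1, with 0 in the 3 others of each group. In ependymal cells, Zic1 and Zic4 were each at 15.01 CPM (2 UMIs each) in female lateral replicate 1 and at 0 in the 3 other lateral samples. Where the 3 others are at 0, any count stands apart by construction, so these cases say little. Ddx3y in oligodendrocytes was at 41.7 CPM in male septal replicate 1.

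The edgeR interaction test of sex and wall called mt-Atp8 in neurons (-5.80), Gm15920 (5.65), Cldn11 (-5.06) and mt-Nd1 (-4.06) in OPCs, and Hba-a2 (5.64), Hbb-bs (5.58), Hba-a1 (5.38), Gm15920 (6.60), mt-Rnr2 (-4.41) and mt-Rnr1 (-7.18) in COPs, as log2 values, female minus male. DESeq2 called 0 genes in OPCs and COPs (164 and 120 at an unadjusted p under 0.05 by edgeR). In both, the male lateral group was 1 sample, so a difference between the sexes cannot be separated from a deviation of that sample. The percent of mitochondrial UMIs over all cells was higher in the lateral wall in both male pairs (mean difference 0.403 percentage points) and lower in both female pairs (-0.227), a difference between the sexes that was not tested.

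Genes present in 1 deposited table alone were left out of all comparisons. Ttr, the transthyretin gene of the choroid plexus, had a row in the replicate 1 table alone, with 857 UMIs in the female lateral, 14003 in the female septal, 2784 in the male lateral and 2700 in the male septal sample, or 73.1, 1347, 230 and 640 CPM of all UMIs. The Cre recombinase row of the replicate 2 table held 4 UMIs in male lateral replicate 2, 3 in female lateral replicate 2 and 0 in both septal samples.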

How the results depend on the processing

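Equal total counts and each deposited table alone were tests chosen after the results were seen. A table alone holds 1 sample per group and leaves 1 residual degree of freedom, so its counts of genes rest on little estimate of spread. Of the log2 fold changes of named genes, 49 kept their side of the threshold with DESeq2 and 10 lost it, 55 and 4 with RLE size factors, and 56 and 3 with no filter on low counts. With equal numbers of cells 23 kept and 23 lost it, and over all omissions of 1 sample 307 and 142. None changed sign. Counts of genes moved far more, and the cause was not tested except where fewer cells, counts or samples enter by construction. Depth limits what small classes can show: equal total counts left 1081 testable neuron genes of 8047.

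With DESeq2, counts between walls were 203 in astrocytes, 46 in the aNSC+TAC+NB class, 49 in neurons, 0 in OPCs, 5 in oligodendrocytes, 11 in microglia (adjusted over 1423 genes, against 8556 by edgeR) and 2 in mural cells and fibroblasts. Between sexes they were 5 in astrocytes, 3 in the aNSC+TAC+NB class, 3 in neurons, 5 in oligodendrocytes and 1 in ependymal, endothelial and mural and fibroblast cells. For the interaction they were 0 in OPCs and COPs, 1 in oligodendrocytes and endothelial cells and 2 in microglia and mural cells and fibroblasts. RLE size factors gave 3 genes between walls in neurons and 6 for the interaction in COPs.

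With no filter on low counts, and in the order astrocytes, aNSC+TAC+NB, neurons, ependymal cells, OPCs, COPs, oligodendrocytes, microglia, endothelial cells and mural cells with fibroblasts, counts were 494, 333, 101, 41, 3, 9, 370, 181, 112 and 5 between walls. They were 83, 206, 11, 11, 12, 3, 279, 145, 87 and 9 between sexes, and 28, 49, 19, 8, 0, 7, 30, 46, 19 and 16 for the interaction. Equal numbers of cells gave between walls 21 in astrocytes, 6 in ependymal cells and 0 in neurons and OPCs, between sexes 1 in oligodendrocytes and 0 in astrocytes, the aNSC+TAC+NB class and microglia, and for the interaction 0 in neurons and COPs. The tested factor alone gave between walls 108 in astrocytes, 18 in neurons, 2 in OPCs and 3 in COPs, and between sexes 2 in the aNSC+TAC+NB class. Equal total counts gave between walls 6 in astrocytes, 4 in ependymal cells and 0 in neurons and OPCs. The replicate 1 table alone gave 911, 55, 49 and 13 in astrocytes, ependymal cells, neurons and OPCs, and the replicate 2 table alone 52 in astrocytes, 35 in ependymal cells and 16 in neurons, while OPCs could not be fitted there.

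Whether the replicate numbers pair the samples is open, and they were not treated as pairs. No label states a pairing, and in astrocytes the correlations of same-numbered deviations were 0.143 for the male and 0.286 for the female walls, and 0.138, 0.037, -0.047 and 0.207 for the other combinations, not all over 0.1. Over all classes they ranged from -0.208 to 0.489, with the highest in the aNSC+TAC+NB class (0.489), oligodendrocytes (0.465) and microglia (0.402). With the number as a replicate block, counts between walls were 116 in astrocytes, 0 in neurons and 7 in OPCs. Between sexes the block gave 2 in the aNSC+TAC+NB class, 1 in ependymal and in endothelial cells and 3 in OPCs, and for the interaction 10 in OPCs and 3 in mural cells and fibroblasts. Lists called with the block were 5 between walls in OPCs and 5 between sexes in COPs, and of the described lists 58 kept their side of the threshold, 4 lost their call and 1, the neuron markers in astrocytes, gained it. Microglial markers in COPs and ependymal markers in microglia were among those that lost it. No gene list was called with an estimated correlation, 0 in all 10 classes for walls and for sexes.

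Leaving out 1 sample at a time gave, in the same order of classes, between walls 14 to 158, 0 to 2, 0 to 149, 7 to 25, 0 to 5, 0 to 2, 0 to 1, 0 to 2, 0 to 2 and 0 to 1 genes. Between sexes it gave 1 to 7, 0 to 5, 1 to 3, 0 to 2, 1 to 10, 0 to 2, 0 to 19, 0 to 4, 0 to 42 and 0 to 2. For the interaction it gave 0 in astrocytes, the aNSC+TAC+NB class and oligodendrocytes, 0 to 45 in neurons, 0 to 4 in ependymal cells, 0 to 8 in OPCs, 0 to 17 in COPs, 0 to 2 in microglia, 0 to 7 in endothelial cells and 0 to 4 in mural cells and fibroblasts. In groups left with 1 sample, that sample was assumed to vary like the others.

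For shares, edgeR on cell numbers gave 2.06 for aNSC+TAC+NB between walls, past the threshold, and changed the sign between sexes for COPs (-0.083) and T cells (-0.014). Omissions of 1 sample changed the sign between walls for oligodendrocytes alone (-0.06 to 0.17). Between sexes the sign changed in all 11 classes: astrocytes -0.02 to 0.66, aNSC+TAC+NB -0.65 to 0.57, neurons -0.46 to 1.13, ependymal cells -0.48 to 0.47, OPCs -1.17 to 0.13, COPs -0.53 to 0.57, oligodendrocytes -0.25 to 0.01, microglia -0.48 to 0.88, T cells -0.75 to 1.01, endothelial cells -0.041 to 0.824, and mural cells and fibroblasts -0.24 to 0.52. The aNSC+TAC+NB share between walls ranged from 2.11 to 2.51.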

Other observations

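The gene groups given here were taken up after their test results were seen. In lateral microglia, all 18 immediate-early genes had higher values than in septal microglia. Examples were the transcription factor genes Fosb (853 ± 228 against 308 ± 93.8 CPM, SD, n = 4) and Egr1 (2348 ± 861 against 928 ± 308) and the cytokine signalling suppressor gene Socs3 (659 ± 214 against 246 ± 97.9). None passed over all genes by edgeR, and 13 rose when adjusted over the list alone (median log2 fold change 0.71, camera adjusted p = 1.08e-10, adjusted p = 0.258 with an estimated correlation). All 9 mitochondrial transcripts tested in microglia also had higher fitted lateral values (median 0.80, camera adjusted p = 0.0463, adjusted p = 0.776 with an estimated correlation). They went opposite ways in the sexes, with a median difference of log2 CPM of 2.90 in males and -0.90 in females. Markers of other cell types moved in the same class. In the lateral wall 5 of 6 markers of activated stem and transit amplifying cells (median 1.22), 11 of 12 endothelial markers (median 0.39) and all 5 red blood cell genes (median 1.04) were higher, and 7 of 9 neuron markers (median -1.01) and 4 of 5 ependymal markers (median -0.57) lower. None passed over all genes. Their camera adjusted p-values were 0.00196, 0.0176, 0.0176, 0.0462 and 0.0463 (adjusted p of at least 0.258 with an estimated correlation), and the red blood cell genes went opposite ways in the sexes (median difference of log2 CPM -0.33 in males and 2.05 in females). For neuron markers this median was 0.005 in males and -0.97 in females. The ependymal markers lost their call with the replicate number as a block (camera adjusted p = 0.0667). In COPs, 19 of 20 cholesterol synthesis genes had higher lateral values, 3 of them when adjusted over the list alone and none over all genes (median 0.70, camera adjusted p = 2.07e-07, adjusted p = 0.711 with an estimated correlation). In the same class 17 of 21 astrocyte markers had lower lateral values, 3 of them when adjusted over the list alone and none over all genes (median -0.81, camera adjusted p = 0.00171, adjusted p = 0.711 with an estimated correlation). All 5 neuron markers (median -3.00) and 7 of 8 microglial markers (median -0.36, but 0.48 in males and -1.04 in females as differences of log2 CPM) were also lower, none over all genes (camera adjusted p = 0.00171 and 0.0425, adjusted p = 0.711 each with an estimated correlation). With the replicate number as a block the microglial markers lost their call (camera adjusted p = 0.109). In the COP class of male septal replicate 2, 34.9% of cells held no COP marker UMI, at a median of 467 UMIs per cell. All 5 red blood cell genes were higher in the lateral wall when adjusted over the list alone (median 3.37, camera adjusted p = 6.79e-05, adjusted p = 0.711 with an estimated correlation). The lateral values were highest in female lateral replicate 2, where Hbb-bs was at 20860 CPM against 586 and 2561 CPM in the other lateral sums. In males the mean differences of log2 CPM were -0.44 for Hba-a2, -0.69 for Hbb-bs and -0.28 for Hba-a1.

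In astrocytes, genes of the Wnt pathway moved both ways. Sfrp1 and Dkk3 rose in the lateral wall over all genes, and of 15 members 6 rose and 2 fell when adjusted over the list alone. Nkd1, a Wnt target and inhibitor, was at 30.8 ± 9.94 lateral and 10.8 ± 2.27 septal CPM. Notum, for a secreted enzyme that inactivates Wnt proteins, was at 53.6 ± 44.5 and 7.91 ± 3.46 CPM. The median of the list was 0.18 (camera adjusted p = 0.0654, adjusted p = 0.732 with an estimated correlation). Of 17 genes of BMP and TGF-beta signalling, Id3 and Id1 rose and Ltbp1 (6.44 ± 3.44 against 27.8 ± 5.73 CPM) fell over all genes, and 3 rose and 1 fell when adjusted over the list alone (median 0.25, camera adjusted p = 0.0636, adjusted p = 0.513 with an estimated correlation).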
